A study of Homo sapiens with 12 samples.

How the data were processed

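RNA-seq read counts were analysed for 12 libraries: parental cells, tumor-initiating cells (TICs) and PRKCI knockdown TICs of the lung cancer cell lines H1703, H1299, CHAGO and CALU, with 1 library per line and state. RNA was extracted with a Qiagen RNeasy kit and libraries were made with a NuGEN kit, per the labels' protocols. The software named is CASAVA 1.4, TopHat 1.4 and HTSeq 0.5.3p3 with genome build hg19, per the submitters' processing notes, which do not say what each was run for. The deposited raw count table holds whole read counts per gene and library, per the file headers. A second deposited table holds mode-normalized values, a score equal to the raw count times 1 factor per library, rounded to whole numbers, per the labels' column names and a comparison of both tables. How the knockdown was made and how TICs were grown are not given in the sources used here. Parental cells with PRKCI knockdown, named in the design text, were not analysed here.

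The count table lists 22506 genes, of which 4044 have no read in any library, and 26 symbols had been turned into dates by a spreadsheet and were left as they stand. Each column was joined to its sample by name, and the column name of the CALU knockdown library differs from its sample title by a letter, while its correlation across genes was 0.918 with CALU TICs and at most 0.738 with another line. Libraries were paired by the line named in the labels. This was checked on the data: after the mean of each state was removed, libraries of the same line correlated at 0.553 to 0.760 (12 pairs) and those of different lines at −0.414 to −0.0601 (36 pairs), across genes.

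The analysis used R 4.3.3. Genes with low counts were removed with edgeR 4.0.16 (filterByExpr with the 3 groups), which left 14008. Counts were scaled with TMM factors and fitted with edgeR's quasi-likelihood model (robust) with a term for state and a term for cell line, on all 12 libraries with 6 residual degrees of freedom, and each comparison was tested two-sided with Benjamini-Hochberg adjustment over all tested genes at 0.05. The common dispersion was 0.489, a biological coefficient of variation of 0.699. Standard errors were taken as the size of the log2 fold change over the square root of the F statistic. A total of 41 gene lists, fixed before the data were examined, was tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 41 lists; camera with an estimated correlation and fry were run as alternatives. Of 807 list symbols, 769 matched as written, 36 through a synonym and 2 not at all. Medians per list come from the edgeR fold changes, and medians per line from differences of log2 CPM. Where a gene had 0 reads the limit of detection was taken as 3 reads. Intervals and limits cover counting error only.

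The rule for named genes was fixed before the data were examined. PRKCI, SOX2, HHAT, SHH, PTCH1, SMO, GLI1, GLI2, GLI3 and ECT2 are always given. For TICs against parental cells and for knockdown TICs against TICs, the rule takes up to 8 called genes with the largest rise and 8 with the largest fall that moved the same way in 4 lines with a mean log2 CPM of at least 2. Where fewer than 5 qualified, the rule filled up to 8 with the genes of smallest p that moved the same way, said to miss the threshold. It also takes up to 4 members of smallest p from each list described. Not every gene the rule takes is printed. Genes outside it are said to be chosen after their values were seen.

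The model was tested on simulated counts for the 14008 genes with 200 changed genes. For TICs against parental cells it recovered 4% of genes changed by 1 on the log2 scale, 68% at 2, 86% at 3 and 90% at 4 (50 genes each), with 6 false calls. For knockdown TICs against TICs it recovered 2%, 68%, 78% and 94%, with 8 false calls, and for knockdown TICs against parental cells 6%, 70%, 92% and 92%, with 5 false calls. The changed genes all had a mean log2 CPM above 2 and the same change in each line. These shares do not cover genes with fewer reads or changes that differ between lines. Real fold changes correlated between lines at 0.0246 to 0.175 in TICs against parental cells and at 0.00563 to 0.0692 after knockdown. Opposite signs between comparisons that share the TIC libraries were measured against 100 simulated sets with no change (40 sets for the shares of the edgeR fit, added after seeing the data), and also between separate pairs of lines.

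Alternatives fixed before the data were examined were DESeq2 size factors and library totals in place of TMM, filters of 1 CPM and 5 CPM in 4 libraries, no line block, each line left out in turn, only the libraries of the compared groups, DESeq2 1.42.0, limma voom, the authors' mode-normalized values (pseudocount 1), an adjusted p of 0.10 and an added minimum log2 fold change of 1. Added after seeing the data were the 2 pairs of lines of like depth, genes at an unadjusted p under 0.01 for the opposite signs, leaving out the CALU knockdown library, and the counts of list members called by DESeq2. GC content and transcript length, and depth, were tested for the cholesterol synthesis and G1/S lists, those with the smallest camera p between TICs and parental cells. Nothing else was left out of the main comparisons.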

Results

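RNA sequencing measured gene expression in 12 libraries from 4 human lung cancer cell lines, given in the labels as H1703, H1299, CHAGO and CALU. Each line was sampled in 3 states with 1 library per line and state. The states were parental cells, tumor-initiating cells (TICs, the cells of a tumor population able to seed new tumors), and TICs in which PRKCI was knocked down. The labels call the parental cells adherent and do not say so of the TICs. PRKCI encodes protein kinase C iota, an atypical protein kinase C that binds the polarity protein PAR6. The 4 lines served as the replicates of each state (n = 4), so the spread behind each test is the spread between lines. The libraries held 54.5 ± 29.4 M counted reads (M, mega) in the parental group, 56.3 ± 36.1 M in the TIC group and 51.5 ± 32.5 M in the knockdown group (mean ± SD, n = 4 each). Depth followed the line and not the state, with 21.2 to 36.1 M reads in the 6 libraries of H1703 and H1299 and 63.8 to 91.8 M in the 6 libraries of CHAGO and CALU. Of 22506 genes listed, 14008 held enough reads to be tested. Levels are counts-per-million values (CPM) after TMM scaling, and differences as log2 fold changes from edgeR with the cell line as a block.

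PRKCI, the targeted gene, was lower in the knockdown library than in the TIC library of each line. Its level went from 342 to 58.1 CPM in H1703, from 199 to 25.8 CPM in H1299, from 608 to 23.2 CPM in CHAGO and from 237 to 41.5 CPM in CALU. The group means were 346 ± 185 CPM in TICs and 37.2 ± 16.1 CPM after knockdown (SD, n = 4), a log2 fold change of −3.15 with a standard error of 0.37, or 8.88-fold lower. The edgeR adjusted p was 0.0489, lower in 4 of 4 lines. PRKCI itself did not differ detectably between TICs and parental cells, at 346 ± 185 against 308 ± 39.1 CPM (SD, n = 4). That log2 fold change was 0.08 with a standard error of 0.34 (edgeR adjusted p = 0.957, higher in 2 lines and lower in 2), and −0.21 without CHAGO. The knockdown call passed narrowly: without each line in turn its edgeR adjusted p was 0.395 (H1703), 0.540 (H1299), 0.0537 (CHAGO) and 0.597 (CALU), without the CALU knockdown library 0.275, without the line block 0.137 and from the libraries of the 2 compared groups alone 0.450. DESeq2 gave an adjusted p of 3.37e-13.

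**Figure D1:**
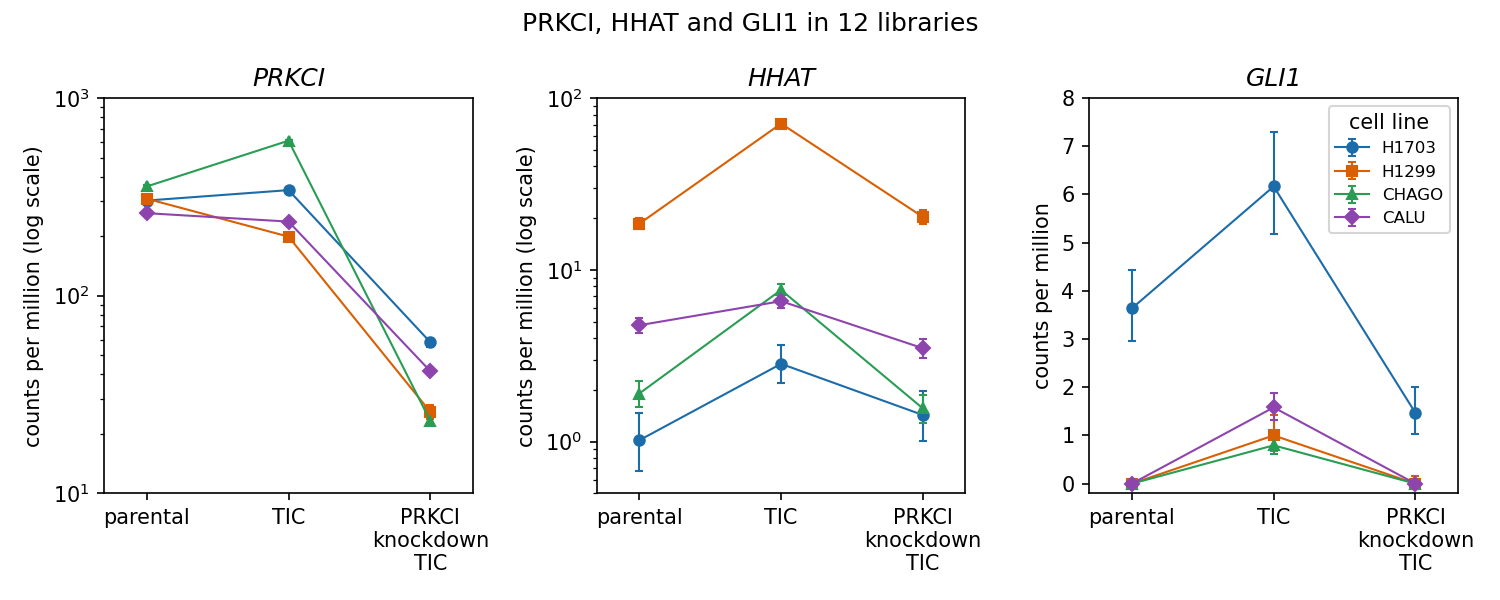
Levels of PRKCI, HHAT and GLI1 in the 12 libraries, in CPM, on a log axis for PRKCI and HHAT and a linear axis for GLI1. Each line and marker is 1 cell line, bars are 95% Poisson intervals of the read count, and the 4 TIC libraries lie above the parental and the knockdown library of their line for HHAT and GLI1.

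The comparison of TICs with parental cells asked which genes differ between these states, whatever the part of adherent growth. KLHL24, a substrate adaptor of a ubiquitin ligase, rose 3.43-fold, from 80.2 ± 30.0 to 278 ± 123 CPM (SD, n = 4), a log2 fold change of 1.78 with a standard error of 0.19. IDS, a lysosomal sulfatase, rose 2.91-fold, from 186 ± 155 to 507 ± 387 CPM (SD, n = 4), a log2 fold change of 1.54 with a standard error of 0.18. Their edgeR adjusted p values were 0.0149 and 0.0212, and each was higher in 4 of 4 lines. VGLL3, a cofactor of TEAD transcription factors named after its values were seen, fell by 2.85 on the log2 scale (standard error 0.28, 7.23-fold lower, edgeR adjusted p = 0.0212), lower in the 3 lines with reads, since H1703 had none. IDS has a near copy in the genome, so its reads are uncertain in origin.

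In all, 4 genes passed an adjusted p of 0.05 in edgeR, 3 higher and 1 lower. At an unadjusted p under 0.05 there were 1652 genes, 803 higher and 849 lower, against 700 that uniform p values would give. Other groupings of these libraries, described below, gave up to 1476 such genes, and up to 1200 where each line was parted. No gene was called without any 1 line, with no line block, within H1703 and H1299 or within CHAGO and CALU, while DESeq2 called 511 genes (323 higher, 188 lower), limma voom 10 and the authors' mode-normalized values 43.

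Several further genes came close to the threshold and moved the same way in 4 of 4 lines. Higher in TICs was WLS, which carries Wnt proteins to the cell surface (log2 fold change 1.68, edgeR adjusted p = 0.0945). SAT1, an enzyme of polyamine breakdown (2.46, 0.0972), P4HA2, a collagen prolyl hydroxylase (2.23, 0.1002), and FTL, the ferritin light chain (1.38, 0.1002), were also higher. Lower in TICs were PLCB4 (−2.61, edgeR adjusted p = 0.0945), the ketone body enzyme OXCT1 (−1.19, 0.1002), the cold-induced RNA-binding gene RBM3 (−1.64, 0.1002) and the snoRNA host gene SNHG1 (−1.60, 0.108). The mitochondrial transcription factor TFAM (−1.07, 0.119), the matrix protein THBS1 (−2.99, 0.142) and the DNA repair gene BRCA1 (−1.26, 0.148) were lower as well. None of the genes in this paragraph passed the threshold in edgeR, while DESeq2 called each of them.

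Lipid synthesis genes were higher in TICs as a group. Of 23 cholesterol synthesis genes tested, 22 were higher, with a median log2 fold change of 1.09 (limma camera adjusted p = 6.99e-12, adjusted p = 0.234 with an estimated correlation). None passed over all genes in edgeR and 12 did in DESeq2, and 15 passed in edgeR adjusted over the list alone, including SC4MOL (MSMO1, log2 fold change 1.69) and SC5DL (SC5D, 1.29). The median was 1.15 in H1703, 0.11 in H1299, 1.62 in CHAGO and 1.57 in CALU. Fatty acid synthesis genes were higher for 16 of 17 (median 0.34, camera adjusted p = 0.00262, adjusted p = 0.226 with an estimated correlation), with 0 past the threshold over all genes in edgeR, 3 in DESeq2 and 3 in edgeR adjusted over the list alone. The last 3 were SCD, the stearoyl-CoA desaturase (1.25), ACSS2 (2.01) and FASN (1.10).

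Genes of the cell cycle were lower in TICs as a group. All 27 G1/S and DNA replication genes tested were lower, with a median log2 fold change of −1.20 (camera adjusted p = 6.99e-12, adjusted p = 0.244 with an estimated correlation), 0 over all genes in edgeR, 5 in DESeq2 and 13 in edgeR adjusted over the list alone. The replication genes MCM3 (−1.31), MCM4 (−1.11) and MCM10 (−1.49) were among the 13. Of 27 G2/M genes 26 were lower (median −1.05, camera adjusted p = 2.11e-09, adjusted p = 0.370 with an estimated correlation), for example HMMR (−1.70), CENPE (−1.35), KIF11 (−1.01) and KIF23 (−1.24), with 0 passing over all genes in edgeR, 2 in DESeq2 and 0 in edgeR adjusted over the list alone. The medians of both lists were 0.04 and 0.41 in CHAGO, against −0.79 and −0.40 in H1703, −1.55 and −1.46 in H1299, and −2.15 and −2.57 in CALU, and the difference between lines was not tested. Replication-dependent histones were lower for 14 of 15 genes (median −0.82, camera adjusted p = 7.26e-06, adjusted p = 0.234 with an estimated correlation), with 0 past the threshold over all genes in edgeR, 2 in DESeq2 and 2 in edgeR adjusted over the list alone. Ribosome biogenesis genes were lower for 22 of 23 (median −0.77, camera adjusted p = 8.33e-07, adjusted p = 0.234 with an estimated correlation), with 0 over all genes in edgeR, 3 in DESeq2 and 3 in edgeR adjusted over the list alone, the last being NCL (−0.77), NOLC1 (−0.93) and DKC1 (−1.03).

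The lists of MAPK feedback targets, immediate early genes, hypoxia response and lysosome genes were higher in TICs. Of 19 MAPK feedback targets, 18 were higher (median log2 fold change 1.01, camera adjusted p = 1.04e-06, adjusted p = 0.244 with an estimated correlation), with 0 over all genes in edgeR, 3 in DESeq2 and 5 in edgeR adjusted over the list alone, among the 5 SPRY2 (1.85) and DUSP6 (2.60), both inhibitors of the pathway. The line medians were 2.97 in CHAGO, 1.02 in CALU, 0.03 in H1299 and 0.00 in H1703. All 18 immediate early genes were higher (median 0.63, camera adjusted p = 0.002, adjusted p = 0.226 with an estimated correlation), 0 over all genes in edgeR or DESeq2 and 0 adjusted over the list alone. Hypoxia response genes were higher for 14 of 18 (median 0.70, camera adjusted p = 0.000109, adjusted p = 0.234 with an estimated correlation), with 0 over all genes in edgeR, 5 in DESeq2 and 6 in edgeR adjusted over the list alone, including P4HA2, BHLHE40 (2.26), P4HA1 (1.66) and the histone demethylase KDM3A (0.86). Lysosome and autophagy genes were higher for 18 of 20 (median 0.62, camera adjusted p = 9.52e-05, adjusted p = 0.234 with an estimated correlation), for example TPP1 (1.45), CTSB (1.48) and LAMP2 (0.77), with 0 over all genes in edgeR, 2 in DESeq2 and 1 in edgeR adjusted over the list alone.

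The lists of matrix metalloproteinases, squamous differentiation, integrins and focal adhesion, and YAP and TEAD targets passed in camera as well. Of 14 matrix metalloproteinase list genes, 11 were higher (median log2 fold change 1.52, camera adjusted p = 0.00543, adjusted p = 0.229 with an estimated correlation), while ADAMTS1, which cleaves aggrecan, was lower (−2.77). Adjusted over the list alone 1 gene was higher in edgeR, TIMP2 (1.34), an inhibitor of these proteases, and 1 lower, ADAMTS1, with 0 over all genes in edgeR and 3 in DESeq2. Most genes of the squamous differentiation list had too few reads to be tested. Of the 8 tested, 7 were higher (median 1.94, camera adjusted p = 0.0027, adjusted p = 0.234 with an estimated correlation). The 7 included KRT15 (2.70), TP63 (3.66) and DSC2 (1.91), with 0 over all genes in edgeR, 3 in DESeq2 and 4 in edgeR adjusted over the list alone. The median was also 1.94 with SBSN, which had no parental reads, set to its bound. Integrins and focal adhesion genes were higher for 17 of 20 (median 0.42, camera adjusted p = 0.00115, adjusted p = 0.244 with an estimated correlation), with ITGA2 (2.51) and ITGA3 (1.17) passing in edgeR adjusted over the list alone, 0 over all genes in edgeR and 2 in DESeq2. Targets of YAP and TEAD were lower for 19 of 21 (median −1.01, camera adjusted p = 0.00384, adjusted p = 0.370 with an estimated correlation), with CYR61 (CCN1, −2.61), JUB (AJUBA, −2.01) and CRIM1 (−1.06) passing in edgeR adjusted over the list alone, 0 over all genes in edgeR and 3 in DESeq2. Without CHAGO the camera adjusted p was 0.0550 for the squamous list and 0.0611 for the integrins, and without CALU 0.171 for the YAP and TEAD targets.

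A further 10 lists passed, and each lost the call without at least 1 line. Interferon-stimulated genes were higher for 22 of 29 (median log2 fold change 0.64, camera adjusted p = 0.000605, adjusted p = 0.510 with an estimated correlation), but their median was 4.93 in H1299 and 0.00 to 0.28 in the other 3 lines, and without H1299 the adjusted p was 0.913. Extracellular matrix genes were higher for 18 of 24 (median 1.01, camera adjusted p = 0.00731, adjusted p = 0.244 with an estimated correlation), with a median of 1.78 in CALU, and lost the call without CALU (0.0745) or H1299 (0.0995). NF-kB and inflammatory cytokine genes (median 0.72, camera adjusted p = 0.0433, adjusted p = 0.570 with an estimated correlation) lost it without CHAGO (0.261) or CALU (0.171). ATF4 and amino acid response genes were lower (median −0.69, camera adjusted p = 0.00543, adjusted p = 0.481 with an estimated correlation), and lost the call without H1299 (0.565). NRF2 targets (median 0.37, camera adjusted p = 0.0116), 3 metallothioneins (0.96, 0.0144), the unfolded protein response (0.20, 0.0285), TGF-beta targets (0.20, 0.033), glycolysis (0.18, 0.0433) and cytosolic ribosomal proteins (−0.14, 0.047) also passed. With an estimated correlation their adjusted p values were 0.247, 0.234, 0.457, 0.234, 0.477 and 0.622 in that order. Calls were lost for NRF2 targets (adjusted p = 0.0830) and metallothioneins (0.0559) without CHAGO, and for the unfolded protein response without H1299 (0.0560), CHAGO (0.124) or CALU (0.183). They were also lost for TGF-beta targets without H1703 (0.0763) or CHAGO (0.0544), for glycolysis without H1299 (0.224) or CHAGO (0.145), and for ribosomal proteins without H1703 (0.0663), H1299 (0.400) or CALU (0.189). Reads of ribosomal protein genes are shared with many pseudogene copies.

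In all, 25 of 41 lists passed with camera's preset correlation, 18 higher and 7 lower, and 0 passed with an estimated correlation, where the adjusted p values of the 25 lay between 0.226 and 0.622. The call stood without each line in turn for 11 of the 25 lists, within H1703 and H1299 for 10 and within CHAGO and CALU for 19. Markers of other cell types did not pass in camera: leukocyte (median −0.05, adjusted p = 0.475), endothelial (−1.01, 0.423), fibroblast (−0.30, 0.552) and lung alveolar and airway markers (0.04, 0.474).

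**Figure D2:**
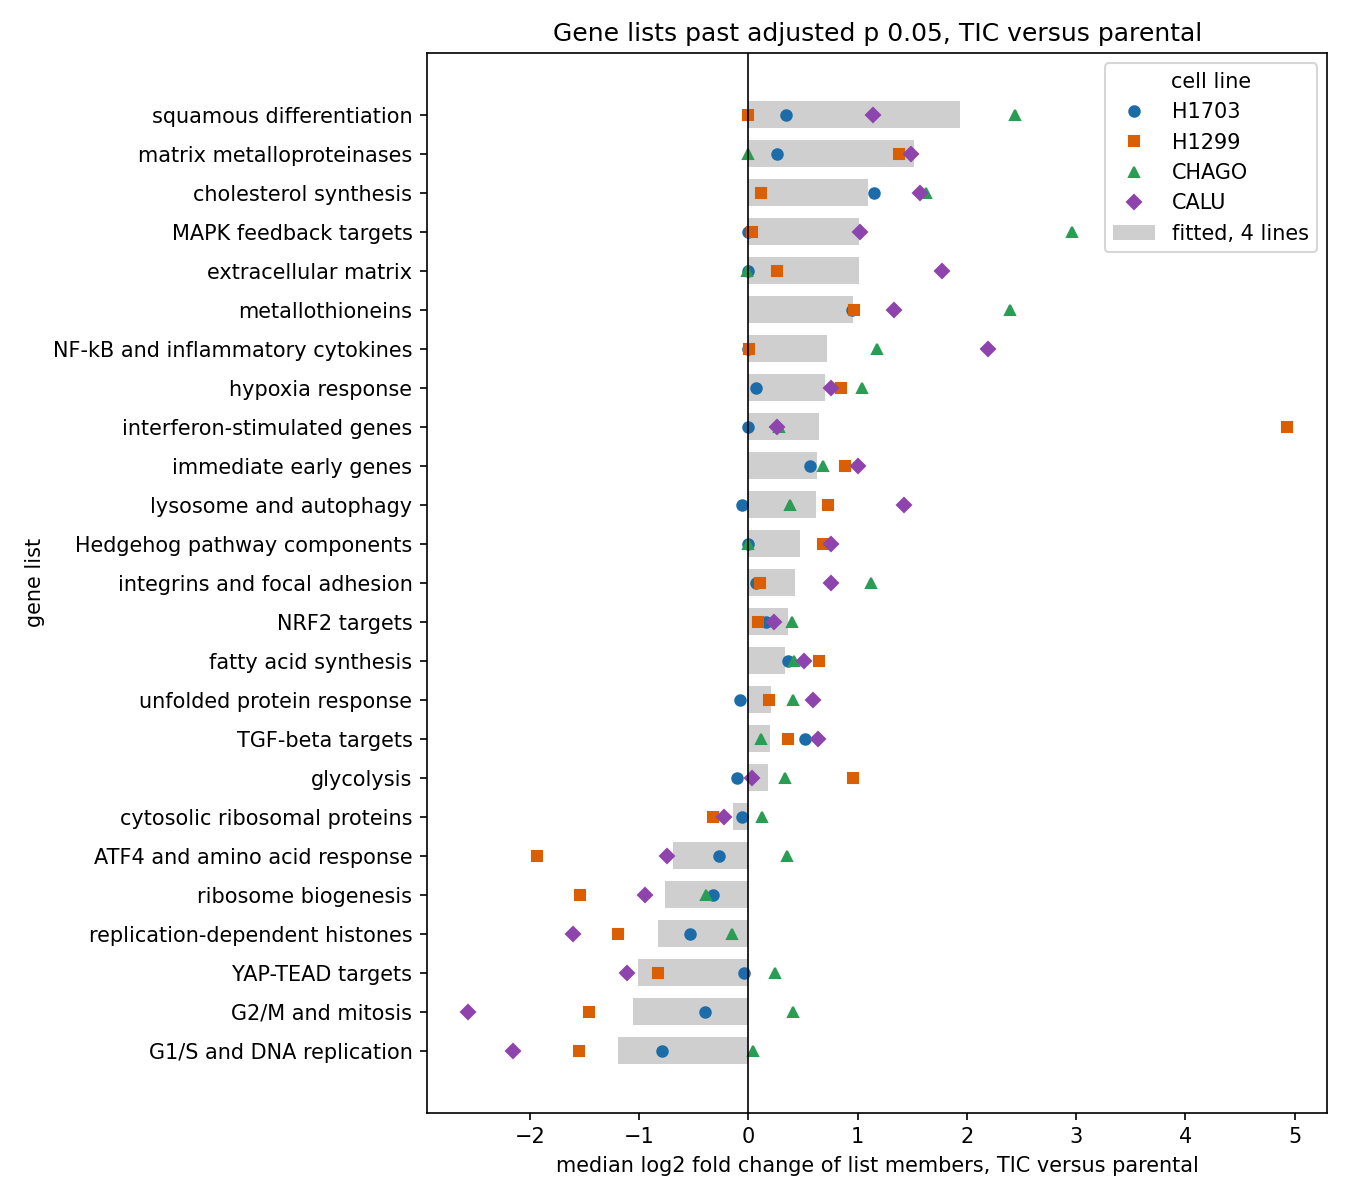
Median log2 fold change of list members, TICs against parental cells, for each gene list past an adjusted p of 0.05 in camera. Grey bars are medians of the edgeR fold changes over 4 lines and points are medians of log2 CPM differences within 1 line; cholesterol synthesis is above 0 and ribosome biogenesis below 0 in each line, while interferon-stimulated genes reach 4.93 in H1299 alone.

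Hedgehog signalling, named in the title of the series, showed higher levels of HHAT and GLI1 in TICs. HHAT, the acyltransferase that palmitoylates Hedgehog ligands, went from 1.02 to 2.84 CPM in H1703, from 18.5 to 71.0 CPM in H1299, from 1.91 to 7.63 CPM in CHAGO and from 4.76 to 6.57 CPM in CALU. Its log2 fold change was 1.49 with a standard error of 0.44, which did not pass in edgeR (adjusted p = 0.247, DESeq2 adjusted p = 0.0161, higher in 4 of 4 lines). GLI1, a transcription factor that is both effector and target of the pathway, had 137 reads in TICs against 100 in parental cells of H1703. In H1299, CHAGO and CALU it had 31, 65 and 131 reads in TICs and 0 in parental cells (edgeR adjusted p = 0.210, DESeq2 adjusted p = 0.0178, higher in 4 of 4 lines), and the parental libraries could have held up to 0.0832, 0.0471 and 0.0327 CPM (before TMM scaling) unseen. The ligand gene SHH had 0 reads in every library. The receptor gene PTCH1 (log2 fold change −0.0049, edgeR adjusted p = 0.998), SMO (1.31, 0.784), GLI2 (−0.61, 0.896), GLI3 (0.79, 0.522) and the pluripotency factor SOX2 (1.26, 0.819) did not pass, and the sign for PTCH1 turned to 0.034 with DESeq2 size factors. ECT2, a RhoGEF bound by PRKCI, was higher in CHAGO (1.17) and lower in the other 3 lines (log2 fold change over 4 lines −0.77, edgeR adjusted p = 0.520).

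As groups, 11 of 18 Hedgehog pathway components were higher in TICs (median log2 fold change 0.47, camera adjusted p = 0.0422, adjusted p = 0.362 with an estimated correlation), with 0 over all genes in edgeR, 2 in DESeq2 and 0 in edgeR adjusted over the list alone. This call was lost without H1299 (adjusted p = 0.152), without CALU (0.221) and with no line block (0.206). Hedgehog target genes (median 0.07, camera adjusted p = 0.475), stem cell and TIC markers (−0.40, 0.475), genes of the 3q26-q29 amplicon that holds PRKCI (0.09, 0.456), partners of atypical PKC (0.03, 0.456), epithelial (0.21, 0.552) and mesenchymal genes (0.40, 0.315) did not pass. Nor did oxidative phosphorylation (−0.20, camera adjusted p = 0.161), p53 targets (0.28, 0.166), neuroendocrine genes (0.51, 0.264), Wnt targets (0.13, 0.340), the Notch pathway (0.06, 0.378) and SRF targets (0.12, 0.556).

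The comparison of knockdown TICs with TICs asked what PRKCI sustains in the tumor-initiating state. Besides PRKCI, MMP3 alone passed in edgeR, and nearly all its reads came from 1 library. MMP3, which encodes the matrix protease stromelysin and is named after its values were seen, stood at 417 CPM in the CALU knockdown library against 1.002 CPM in CALU TICs, and at 0.309 CPM or less in the other knockdown libraries (log2 fold change 8.43, standard error 0.65, edgeR adjusted p = 0.0154, higher in 3 of 4 lines). Without the CALU knockdown library its log2 fold change was 4.55 (edgeR adjusted p = 0.999). At an unadjusted p under 0.05 there were 600 genes, 292 higher and 308 lower, fewer than the 700 that uniform p values would give. Other groupings of these libraries that part each line, described below, gave at most 471 such genes, but groupings that do not gave up to 1221. DESeq2 called 11 genes, 4 higher and 7 lower, including PRKCI but not MMP3, limma voom called 1, and 0 were called without the CALU knockdown library, within either pair of lines of like depth, with the line block left out or with a filter of 1 or 5 CPM. Without CHAGO 1 gene was called, and 0 without H1703, H1299 or CALU.

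Some genes moved the same way in 4 of 4 lines after knockdown without passing in edgeR. Lower were ARF3, a small GTPase of the Golgi (log2 fold change −1.40, adjusted p = 0.713), the G-protein subunit GNAI2 (−1.29), the heparan sulfate polymerase EXT2 (−1.14), CKAP4 (−0.85), the inositol phosphate kinase PPIP5K2 (−0.91), the polarity GTPase CDC42 (−0.71) and the complement inhibitor CD59 (−0.66). Higher were the ciliary transport gene WDR35 (1.01), ZNF828 (CHAMP1, 1.26), NOL9 (0.93), DUSP16 (1.10), AASDHPPT (0.60), SMAD5 (0.55), the peptidase ERAP1 (0.89) and TXNDC9 (0.97). Apart from ARF3 each had an edgeR adjusted p of 0.980, while DESeq2 called ARF3, GNAI2, EXT2 and WDR35.

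In the CALU knockdown library, several cytokine, protease and serpin genes reached high levels. From TICs to knockdown TICs of CALU, IL8 (CXCL8) went from 114 to 6540 CPM, CXCL1 from 52.6 to 3470 CPM, IL1B from 214 to 1790 CPM and IL6 from 8.48 to 497 CPM. MMP1 went from 974 to 17830 CPM and was the most abundant gene of that library with 1.57% of its reads, and SERPINB2 went from 131 to 5996 CPM. The other lines held less, and IL8 and MMP1 moved both ways there. IL8 went from 30.1 to 78.5 CPM in CHAGO but from 4.41 to 0 CPM in H1703 and from 0.194 to 0 CPM in H1299. MMP1 went from 16.8 to 50.9 CPM in H1299 and from 0 to 0.648 CPM in CHAGO, but from 3.11 to 0.811 CPM in H1703. Neither IL8 nor MMP1 passed in edgeR. IL6 also rose in CHAGO, from 45.8 to 119 CPM, and had no reads in H1703 or H1299. CXCL1, IL1B and SERPINB2 fell in none of the other lines after knockdown, but stayed at 1.67 CPM or less there. These genes apart from MMP3 were chosen after their values were seen. They rest on the CALU knockdown library, whose column name differs from its sample title by a letter. The NF-kB list as a whole was higher for 19 of 20 genes (median log2 fold change 0.72), with line medians of −0.71, 0.21, 0.72 and 3.11 in H1703, H1299, CHAGO and CALU, and did not pass in camera (adjusted p = 0.267).

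**Figure D3:**
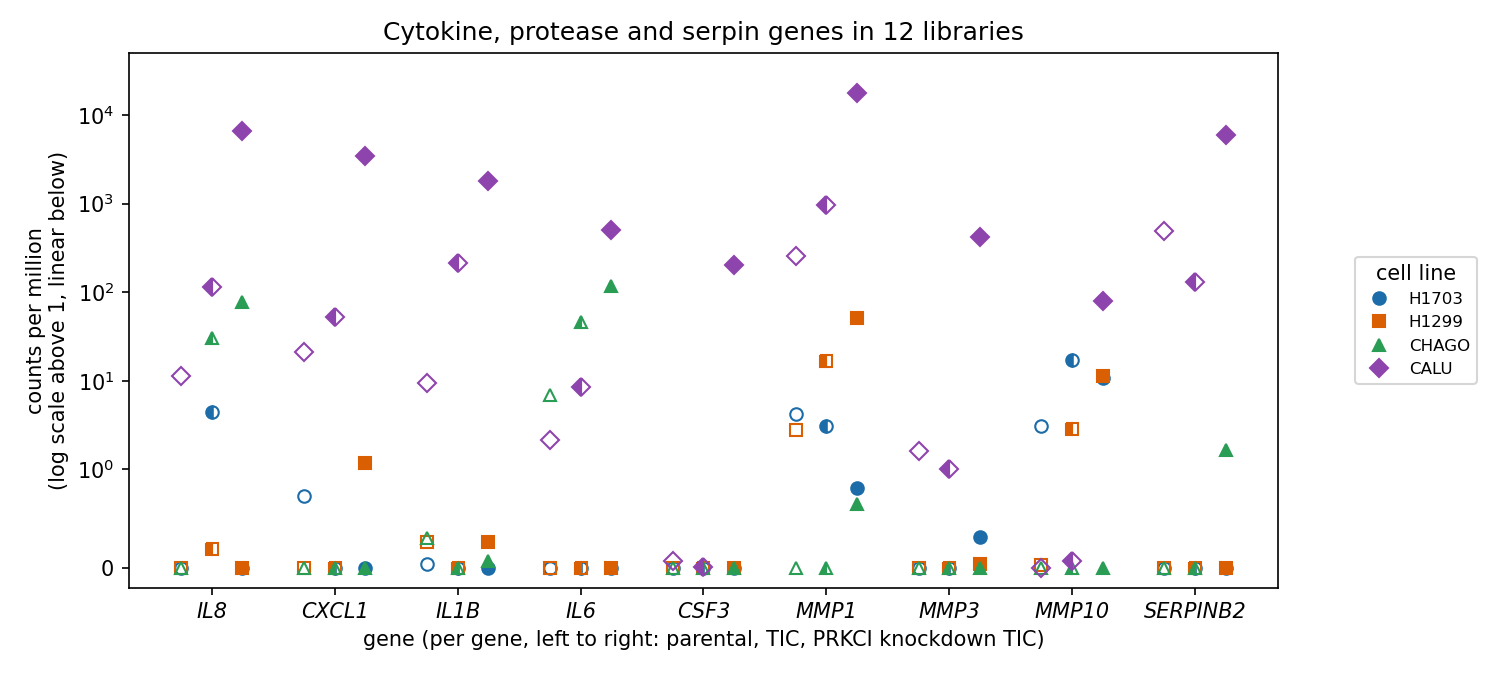
CPM of 9 cytokine, protease and serpin genes in the 12 libraries, on an axis that is logarithmic above 1 and linear below. Per gene, open, part-filled and filled markers are parental, TIC and PRKCI knockdown TIC libraries, and for each gene the filled CALU marker is the highest value, up to 17830 for MMP1.

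HHAT and GLI1, higher in TICs, were lower after knockdown in each line. HHAT went to 1.43 CPM in H1703, 20.3 CPM in H1299, 1.56 CPM in CHAGO and 3.49 CPM in CALU, near its parental levels, a log2 fold change against TICs of −1.53 with a standard error of 0.44 (edgeR adjusted p = 0.980, DESeq2 adjusted p = 0.138, lower in 4 of 4 lines). GLI1 had 38 reads in the H1703 knockdown library and 0 in those of the other 3 lines (edgeR adjusted p = 0.980, DESeq2 adjusted p = 0.119). Adjusted in edgeR over the list of Hedgehog components alone GLI1 had an adjusted p of 0.0352 and HHAT 0.0523, so 1 of 18 passed there and 0 over all genes. The list as a whole had a median log2 fold change of −0.58 and did not pass (camera adjusted p = 0.134). SOX2 (log2 fold change −1.95, edgeR adjusted p = 0.980), PTCH1 (0.18, 0.993), SMO (0.32, 0.996), GLI2 (2.11, 0.980), GLI3 (−0.25, 0.987) and ECT2 (0.16, 0.993) did not pass. SOX2 was lower in each line with reads, and CALU had none. It went from 3.38 to 1.04 CPM in H1703, from 38.8 to 6.09 CPM in H1299 and from 5.57 to 2.35 CPM in CHAGO. With no line block the signs turned for PTCH1 (−0.31), SMO (−1.53) and GLI2 (−0.68), and for PTCH1 without H1703 (−0.53) and SMO without CHAGO (−1.45) as well.

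Of the 41 lists, 1 passed after knockdown: cytosolic ribosomal proteins were lower for 28 of 30 genes by a small amount (median log2 fold change −0.18, camera adjusted p = 0.0207, adjusted p = 0.982 with an estimated correlation), with 0 genes over all genes in edgeR or DESeq2 and 0 adjusted over the list alone. The call was lost without H1299 (adjusted p = 0.466), without CALU (0.308), without the CALU knockdown library (0.376), within H1703 and H1299 (0.549) and within CHAGO and CALU (0.154). The lists with the smallest camera p between TICs and parental cells had medians near 0 after knockdown, 0.02 for cholesterol synthesis (camera adjusted p = 0.923), 0.03 for G1/S (0.656) and 0.06 for G2/M genes (0.531). Ribosome biogenesis (0.22, 0.108), lysosome genes (−0.39, 0.215), the squamous list (−0.58, 0.698, with a mean of 0.29), matrix metalloproteinases (0.95, 0.731) and extracellular matrix genes (−0.48, 0.429) did not pass either.

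Knockdown TICs compared with parental cells gave 5 genes in edgeR, 3 higher and 2 lower. KLHL24 (log2 fold change 1.75, adjusted p = 0.0165) was higher again in knockdown TICs, as was MMP3 (7.74, 0.0165), again from the CALU knockdown library. PRKCI (−3.07, 0.0275) and CRIM1 (−1.85, 0.0484), a transmembrane regulator of BMP signalling named after its values were seen, fell. At an unadjusted p under 0.05 there were 1505 genes, DESeq2 called 395, and 0 passed without H1703, H1299 or CALU or within either pair of lines of like depth, and 2 without CHAGO. Cholesterol synthesis genes were higher for 22 of 23 (median 0.87, camera adjusted p = 4.96e-11, adjusted p = 0.297 with an estimated correlation) and G1/S genes lower for 26 of 27 (−1.07, camera adjusted p = 4.31e-10, adjusted p = 0.353 with an estimated correlation), with 0 genes of either over all genes in edgeR, 10 and 5 in DESeq2, and 11 and 15 in edgeR adjusted over the list alone. In this comparison 21 lists passed, 14 higher and 7 lower, and 0 with an estimated correlation.

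Whether knockdown turns back the TIC pattern was asked by setting both comparisons side by side. All 4 genes called in TICs had the opposite sign after knockdown (4 of 4, exact 95% interval from 39.8%), as had 9058 of 14008 tested genes (64.7%) and 394 of 511 genes (77.1%) at an unadjusted p under 0.01. In 40 simulated sets with no change both shares were higher, with means of 66.6% over all genes and 90.5% at an unadjusted p under 0.01, and each set lay above the observed share, though only 111 genes on average had such a p in those sets. Both comparisons use the same TIC libraries, which by itself produces opposite signs: across genes, which are not independent replicates, r was −0.466, against a mean of −0.498 in simulated data with no change. The covariance was −0.362 against a simulated mean of −0.307. It was more negative than in each of 100 simulated sets (lowest −0.329), while r was less negative than in each (highest −0.469). When TIC effects from 2 lines were set against knockdown effects from the other 2 lines, r lay between −0.0876 and −0.0106 and 52.4% of genes had opposite signs on average. The mean covariance between such separate lines was −0.0644. Higher in TICs and lower after knockdown in 4 of 4 lines were 247 genes, where independent lists would share 83.2 and simulated data with shared libraries gave 151 on average and 188 at most. The reverse order held for 242 genes, where independent lists would share 90.8 and simulated data gave 143 on average and 172 at most. Genes moving the same way in both comparisons also exceeded the simulated counts, with 37 higher in both against 9.25 and 28 lower in both against 9.49.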

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

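Chosen only after the result was seen were the tests for a library of another cell line and for the counting error of HHAT.

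Among 60 sets of 4 line values, 4 held a line far from the other 3, where chance gives 3 at 1 in 20. The log2 difference of IDS between TICs and parental cells was 2.02 in H1299, apart from 1.33 to 1.43 in the other lines. For MMP3 it was −0.68 in CALU and 0 in the other lines, which had no reads. The median of the extracellular matrix list was 1.78 in CALU and −0.01 to 0.26 in the other lines. The median of the interferon-stimulated genes was 4.93 in H1299 and 0 to 0.28 in the other lines. GLI2 was higher in TICs in CHAGO, by 1.44 on the log2 scale, and lower in the other lines, at −1.22 to −0.75, and this difference between lines was not tested.

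Cholesterol synthesis genes were higher and G1/S genes lower in TICs. Removing the trend of fold changes with GC content and transcript length kept at least 98.2% of both medians, and both lists still passed in camera (adjusted p = 6.62e-12 and 1.63e-11), which argues against that trend as the whole cause. Thinning all libraries to 21.2 M reads (M, mega) kept at least 94.9% and both calls in camera (adjusted p = 3.44e-11 and 3.4e-12). Depth followed the line, which the fit blocks, and thinning lowers all genes of a library alike. The thinning could therefore hardly have changed either list, and its result adds little. A tumor-initiating state with more sterol synthesis and less division is a candidate explanation, but both parts were not seen together in each line, since cholesterol genes had a median of 0.11 in H1299 and G1/S genes 0.04 in CHAGO, and neither list passed with an estimated correlation. The labels call the parental cells adherent and do not say so of the TICs. A difference in attachment, like any other in culture, would go with the state in every line. It cannot be told apart from the state here and stays open, untested.

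IL8, CXCL1, IL1B, MMP1, MMP3 and SERPINB2 were far higher in the CALU knockdown library than in the other 11. IL6 was highest there as well, at 497 CPM, but also reached 119 CPM in CHAGO knockdown TICs. The protease gene PLAU was unlike them, at 107 CPM in the CALU knockdown library and 183 CPM in H1299 knockdown TICs. Leukocytes in that culture would bring their abundant transcripts, but 5 leukocyte genes (PTPRC, TYROBP, FCER1G, LYZ and CD52) summed to 4.26 CPM there, all of it FCER1G, against 1.28 CPM in CALU TICs, while IL8 alone stood at 6540 CPM. A library of another of the lines is argued against by its correlation across genes with CALU TICs (0.918), which exceeded the highest with another line (0.738) by 0.180. An effect of losing PRKCI in CALU and an accident of that culture both stay open, since there is 1 such library, and the former remains a hypothesis.

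HHAT and GLI1 were higher in TICs and lower after knockdown in 4 of 4 lines. Counting error of HHAT is argued against, as the 95% Poisson intervals of its TIC library and its partner were separate in 8 of 8 comparisons. The shared TIC libraries cannot be told apart from a PRKCI effect here: 0 of 100 simulated sets held as many mirrored genes as the data, but the sets contain no real effects and genes moving the same way in both comparisons exceeded them as well. With TIC effects from 2 lines and knockdown effects from the other 2, which share no library, HHAT had log2 values of 0.95 to 1.96 and −2.03 to −0.94, but a gene mirrored in 4 of 4 lines keeps both signs in any such choice of lines, whatever the cause. That PRKCI sustains HHAT and GLI1 in TICs is a hypothesis that may hold, and neither gene passed in edgeR over all genes, while DESeq2 called both in TICs and neither after knockdown.

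Other groupings of the same libraries were fitted for each comparison, 35 splits of 8 libraries in each case. The libraries are paired by line, so only the 8 splits that part each pair compare with the real split, which is too few for a share under 0.05. The bound of 5% written beforehand for all splits was wrong for this reason. The other splits keep both libraries of at least 2 lines on 1 side. For TICs against parental cells the real split gave 4 genes against 0 in the highest other of the 8, and 25 lists against 19, with 1 of 8 splits (the real split) as large for each. For knockdown TICs against TICs it gave 2 genes against 1 (1 of 8 splits as large), namely PRKCI, the targeted gene, and MMP3, whose reads are nearly all from the CALU knockdown library. For its lists the real split gave 1 against 4, and 5 of 8 splits were as large. For knockdown TICs against parental cells it gave 5 genes against 1 (1 of 8 splits as large). At an unadjusted p under 0.05 the real splits gave 1652, 600 and 1505 genes in that order of comparisons. The highest other of the 8 gave 1200, 471 and 1006 such genes. Over all 35 splits the highest other values at that p were 1476, 1221 and 1171 genes. For called genes the highest other values over all 35 were 0, 1 and 1, and for lists 21 and 12 in the first and second comparison. The split with 12 lists set H1703 and CHAGO against H1299 and CALU and gave several times the real count. Each split was fitted on all 12 libraries with the line block, so this split compares changes from parental cells between these lines. Its count points to changes from parental cells that differ between lines.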

How the results depend on the processing

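Chosen after seeing the data were the settings with H1703 and H1299 only, CHAGO and CALU only, without the CALU knockdown library, and the genes at an unadjusted p under 0.01. The test finds few small changes, as simulated changes of 1 on the log2 scale were recovered in 4% of genes for TICs against parental cells. The cause of the shifts was not tested, except that leaving out libraries also removes residual degrees of freedom. For TICs against parental cells the count of 4 genes became 0 with no line block, 2 groups only, H1703 and H1299 only, CHAGO and CALU only and without each line (0 to 0). It became 511 with DESeq2, 10 with limma voom, 43 with the authors' mode-normalized values and 11 at an adjusted p of 0.10. For knockdown TICs against TICs the count of 2 became 0 with filters of 1 CPM and 5 CPM, with no line block, 2 groups only, either pair of lines and without the CALU knockdown library, 0 to 1 without each line, 11 with DESeq2, and 1 with limma voom and with mode-normalized values. For knockdown TICs against parental cells the count of 5 became 8 with DESeq2 size factors, 3 with a filter of 1 CPM, 0 with no line block, 2 groups only and either pair of lines, 395 with DESeq2, 20 with mode-normalized values, 9 at an adjusted p of 0.10, and 0 to 2 without each line.

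The log2 fold change of PRKCI after knockdown stayed negative in each setting and missed the threshold with 2 groups only (−3.15), no line block (−3.22), without the CALU knockdown library (−3.35) and without each line (−3.38 to −2.65). The 25 lists for TICs against parental cells became 0 with an estimated correlation, 5 with fry (cholesterol synthesis, fatty acid synthesis, immediate early genes, matrix metalloproteinases and hypoxia) and 11 with H1703 and H1299 only. The 1 list after knockdown became 0 with an estimated correlation, fry, H1703 and H1299 only and without the CALU knockdown library, 4 other lists with CHAGO and CALU only, and 0 to 2 without each line. Signs turned for PRKCI in TICs against parental cells without 1 line (−0.21 to 0.33), for PTCH1 in TICs with DESeq2 size factors (0.034), DESeq2 (0.033), no line block (0.26) and without each line (−0.46 to 0.27). After knockdown they turned for PTCH1 with no line block (−0.31) and without each line (−0.53 to 0.87), SMO with 2 groups only (−0.24), no line block (−1.53) and without each line (−1.45 to 2.06), and GLI2 with no line block (−0.68). The Hedgehog target list turned with H1703 and H1299 only (camera adjusted p = 0.540 in TICs, 0.919 after knockdown). The share of called genes with opposite signs could not be given with no line block or without any line, as 0 genes were called, and was 4 of 4 with library totals only. With library totals only, 24 of the 25 lists kept their call (glycolysis, adjusted p = 0.0534, did not), and the median of all genes shifted to −0.110 for knockdown TICs against parental cells (TMM −0.048).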

Other observations

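The genes named in the next 2 paragraphs, and the lists tested after them, were chosen after the main comparisons were seen; the tests of the lists were written down before their own results were seen.

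H1299 TICs carried an interferon signature, while the few interferon genes examined had no reads in them. Other interferon genes were not examined. The helicase gene IFIH1, which senses double-stranded RNA, stood at 118 CPM in parental H1299 cells, 642 CPM in TICs and 1018 CPM in knockdown TICs. IFIT1 went from 3.22 to 244 and 494 CPM, IFI6 from 7.72 to 685 and 786 CPM, and DDX58 (RIGI) from 42.3 to 308 and 455 CPM. IFNA1, IFNB1, IL28A, IL28B and IL29 had no reads in parental cells or TICs of H1299, and IFNB1 had 1.10 CPM in its knockdown library. In the other lines IFIH1 lay between 5.81 and 84.8 CPM in each library, but some such genes were also higher in CALU TICs than in CALU parental cells, with IFI6 at 254 against 22.5 CPM and IFI44L at 143 against 26.4 CPM, while IFIT1 was lower there, at 19.4 against 43.5 CPM.

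HHAT and GLI1 were among 15 mirrored genes, which moved one way in TICs and the other way after knockdown in 4 of 4 lines with an unadjusted edgeR p under 0.01 in both. Without the limit on p there were 489. TRIB2, a pseudokinase gene, had log2 fold changes of 3.19 and −2.43, CD59 0.62 and −0.66, and EXT2 0.90 and −1.14. WDR35, a gene of the intraflagellar transport that cilia need, had −0.98 and 1.01, NOL9 −1.05 and 0.93, and TFAM −1.07 and 0.68. None of these passed in edgeR after adjustment over all genes in either comparison, while DESeq2 called each of them in TICs and TRIB2, EXT2 and WDR35 after knockdown, and the shared TIC libraries produce part of such mirroring.

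KLHL24 was among the genes called in TICs, and a candidate explanation is higher activity of FOXO factors, which respond to low growth signalling. Of 15 FOXO target genes, 13 were higher in TICs, with a median log2 fold change of 0.66 and positive medians in 4 of 4 lines (camera p = 0.000918, p = 0.0613 with an estimated correlation, fry p = 0.0325), including CCNG2 (1.42) and PNRC1 (1.10), which were the 2 passing in edgeR adjusted over the list alone, with 0 over all genes in edgeR, while DESeq2 called both. KLHL24 was left out of the list, and these p values are unadjusted. The list rose as the hypothesis predicts, but the call was lost with an estimated correlation. As the list was chosen after the main comparisons were seen, its rise does not show why KLHL24 rose. The list of MAPK feedback targets was also higher in TICs (median log2 fold change 1.01), and growth signalling itself was not measured. After knockdown the median of the FOXO targets was −0.11.

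A lower sterol load of TICs might account for the higher cholesterol synthesis genes, and LXR targets, which fall when sterols are scarce, would then be lower. The median log2 fold change of the 5 LXR targets with enough reads, from a list of 8, was 0.38, and their median was positive in 2 of 4 lines. That spread between lines neither excludes nor bears out the explanation.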
